A study of Nannochloropsis oceanica with 18 samples.

How the data were processed

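Polyadenylated RNA from 18 flask cultures of Nannochloropsis oceanica was sequenced as paired reads of 150 bases. The deposited tables hold, per gene and library, expected counts and TPM. The expected counts, as deposited by the authors, are estimated read counts with no normalization; at least 96.3% of values were whole numbers in every library, and values were rounded before testing. The TPM values (transcripts scaled for gene length and library total, deposited by the authors) sum to the same total in each of the 18 libraries. The submitters' processing notes name Trim Galore, STAR, Picard and Salmon; versions, the genome build and the annotation are not given in the sources used here. Each library has its own column, so replicates were not pooled. Of the 10493 genes in the tables, 10333 carry nuclear IDs, 125 are plastid genes and 35 mitochondrial genes. The reference table held 160 organelle symbols, all 160 of which matched, and no names for the nuclear IDs.

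Total counts were 14614662 to 18156737 per library. CPM values are counts scaled to the library total, with the TMM factor where a gene is named. Floors used for groups with 0 counts were 3 counts in each library of the group. They cover counting error only, since reads without molecular identifiers are not independent molecules. Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust estimation, after TMM scaling (factors 0.894 to 1.08) and the filterByExpr filter, which removed 581 genes and left 9912 (9858 nuclear, 36 plastid, 18 mitochondrial). The 6 groups of 3 were fitted together without covariates, so that all groups share 1 estimate of the spread. Adjusted p values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p below 0.05. There were 11 comparisons: the KO-labelled and OE-labelled strains against wild type and against each other at each light level, high against normal light in each strain, and the difference of each manipulated strain's light response from that of wild type. Groups, comparisons, tests, alternatives and the rule for naming genes were set before the data were examined. Exceptions are the tests, alternatives and genes named as not planned or as chosen after the data or a result were seen.

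The rule named NO07G02030 first, then per comparison the 2 nuclear IDs with the largest rise and the 2 with the largest fall among called genes with a group mean of at least 10 CPM and no overlap between the compared groups (no overlap condition for the light response differences). Organelle genes with symbols were named by the same rule, with further list members given as examples, and called genes among the 10 tested IDs on each side of NO07G02030 were named too. Of 22 gene lists written in advance, 19 matched 0 genes. Nuclear genes carry IDs without names, so lists of nuclear genes could not match. The list of cytosolic and organellar ribosomal proteins also matched 0, although the data hold 16 mitochondrial ribosomal protein genes. A match of 0 therefore does not mean that such genes are absent. Chaperones and heat shock had 3 tested members, under the minimum of 5, and was not run. Photosystems and photosynthetic electron transport (8 tested members) and plastid-encoded genes by symbol (26) were run. Another 5 lists, chosen after seeing the data, hold plastid gene expression (9), plastid photosynthesis (13), plastid protein quality and transport (6), mitochondrial respiratory chain (13) and mitochondrial ribosomal protein genes (5). The plastid lists share members, since all draw on the same 36 tested plastid genes, so their results are not separate evidence. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists within a comparison.

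Alternatives were RLE scaling, DESeq2 1.42.0, no filter, a filter at 5 CPM in 3 libraries, the replicate number as a block and a fit of the compared groups only. Others were limma with a trend on log2(TPM + 1) and log2(TPM + 0.1) with a filter at 1 TPM, limma on log2(TPM + 1) without it, and each library left out in turn. The organellar share of each library as a covariate, and leaving out HL_KO replicate 2 and HL_WT replicate 1 together, were chosen after seeing the data. Single values were compared with exact permutation tests, for which 3 against 3 allows no p under 0.1. The method was tested on simulated data with 200 changed genes of 9912: from 21% to 65% of 2-fold changes and from 79% to 95% of 4-fold changes were recovered, and 2.19% to 7.41% of calls were false. The simulation drew genes independently with 1 spread per gene for all libraries, as the fitted model assumes. The real groups differ in spread, so these rates check the calculation and say little about false calls in the real libraries.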

Results

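Messenger RNA was sequenced from Nannochloropsis oceanica strain IMET1, a unicellular marine alga that stores oil. The 18 libraries fell into 6 groups of 3. The groups crossed 3 strains with 2 light levels. The strains were the wild type (WT), a strain whose labels name a knockout of the nuclear gene NO07G02030 (KO) and a strain whose labels name its overexpression (OE). Flask cultures were kept for 8 days at normal light (NL, about 50 µmol photons per square metre per second) or high light (HL, about 300), and the labels describe 3 biological replicates. Total counts ran from 14614662 to 18156737 per library. Group means were 17737067 (NL_OE), 17458007 (HL_OE), 16177276 (NL_WT), 16001345 (HL_WT), 15365674 (NL_KO) and 15116871 (HL_KO). Of the 10493 genes in the table, 9619 to 9827 had at least 10 counts in a library. The nuclear genes carry IDs that the files do not pair with names, so nuclear genes are given by ID. The plastid and mitochondrial genes carry symbols.

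The manipulated gene was examined first, as a check of the labels. NO07G02030 stood at 29.1 ± 3.11 TPM in NL_WT, 21.8 ± 9.83 in NL_KO and 27.6 ± 1.72 in NL_OE (mean ± SD, n = 3). At high light it stood at 18.3 ± 5.78 TPM in HL_WT, 23.3 ± 3.69 in HL_KO and 26.5 ± 1.20 in HL_OE. Its transcript was called neither lower in the libraries labelled KO nor higher in those labelled OE. Against WT the log2 fold change was -0.37 (SE 0.22, adjusted p = 0.439, edgeR) for KO and -0.20 (SE 0.22, adjusted p = 0.554, edgeR) for OE at normal light. At high light it was 0.44 (SE 0.22, adjusted p = 0.272, edgeR) for KO and 0.41 (SE 0.22, adjusted p = 0.155, edgeR) for OE. Two-sided exact permutation tests of TPM gave p = 0.4, 0.7, 0.3 and 0.1 for the same 4 comparisons, and 0.1 is the smallest p that 3 against 3 allows. The transcript level therefore does not show the change that the label overexpression names, so a direction drawn from the labels below is the direction of the label only, and the strains are called KO-labelled and OE-labelled throughout. How the 2 strains were made is not given in the sources used here. Without NL_KO replicate 1, the KO-labelled libraries at normal light were lower by a log2 fold change of -0.72 (adjusted p = 0.0394, edgeR).

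**Figure D1:**
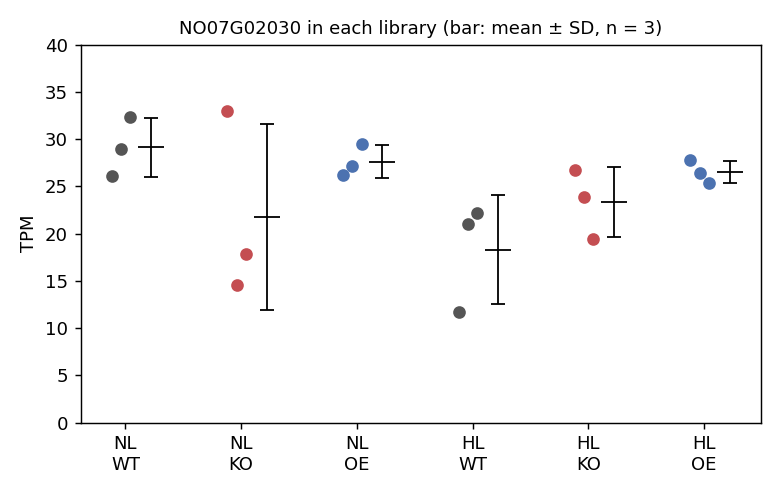
TPM of NO07G02030 (vertical axis) in each of the 18 libraries, by group (horizontal axis); points are libraries and bars are the mean ± SD of 3. The OE-labelled means, 27.6 TPM at normal and 26.5 TPM at high light, lie within the range of the other groups' libraries.

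Replicates of the OE-labelled strain were far more alike than those of the other strains. Pearson correlations of log2 CPM between replicates were 0.990 to 0.995 in HL_OE and 0.993 to 0.995 in NL_OE. They were 0.910 to 0.963 in HL_KO, 0.936 to 0.977 in NL_KO, 0.944 to 0.993 in HL_WT and 0.966 to 0.985 in NL_WT. The biological coefficient of variation over all tested genes was 7.02% in NL_OE and 8.40% in HL_OE. It was 18.5% in NL_WT, 27.9% in HL_WT, 27.5% in NL_KO and 35.1% in HL_KO. The first principal component held 46.6% of the variance. Scores on it lay between 43.5 and 48.2 for the 6 OE-labelled libraries and between -56.8 and 7.68 for the other 12. Within HL_WT, replicates 2 and 3 scored -8.18 and -9.74 and correlated at 0.993, and replicate 1 scored -53.4. The wide spread of HL_WT therefore rests on replicate 1. Organelle transcripts were counted in polyadenylated RNA, so their counts may depend on what that selection kept of them. Organelle differences below are differences in these counts, and their cause was not tested. The organelle share, as organelle counts in CPM of the library total, was 64.7 ± 31.7 in HL_OE and 83.4 ± 48.5 in NL_OE. It was 141 ± 82.3 in HL_WT and 124 ± 33.5 in NL_WT, and 174 ± 77.5 in HL_KO and 253 ± 123 in NL_KO. HL_KO replicate 2 and HL_WT replicate 1 had the lowest mean correlations with their own groups within the KO-labelled and WT strains, 0.921 and 0.944.

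**Figure D2:**
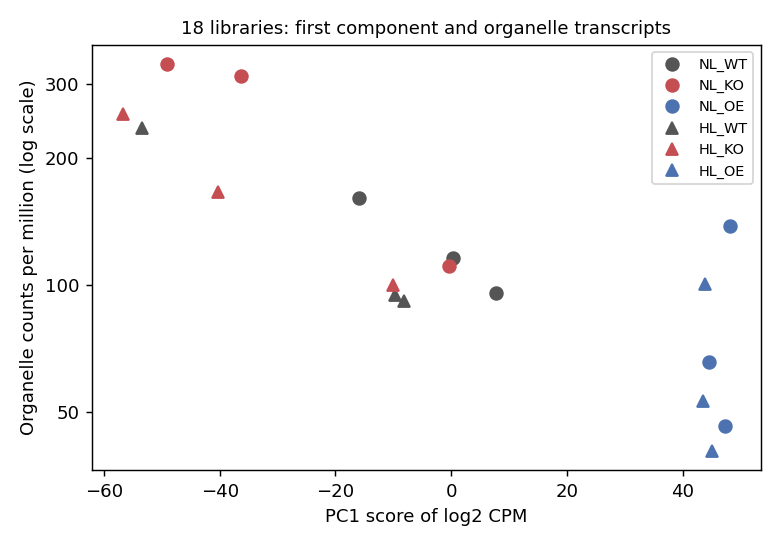
Score on the first principal component of log2 CPM (horizontal axis) against the organelle share in CPM (vertical axis, log scale) for the 18 libraries; circles are normal light and triangles high light. The 6 OE-labelled libraries sit together at 43.5 to 48.2, while replicates of the other groups spread over as many as 48.7 units within a group.

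**Figure D3:**
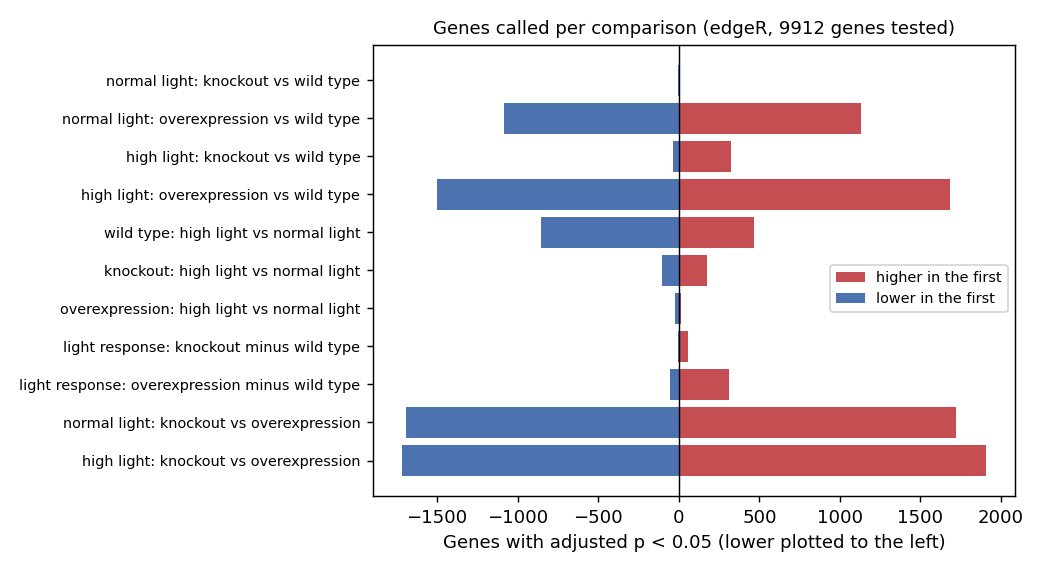
Number of genes with an adjusted p below 0.05 (horizontal axis) in each of the 11 comparisons, of 9912 tested; genes higher in the first-named group point right and lower ones left. Counts run from 13 genes for KO-labelled against WT at normal light to 3623 for KO-labelled against OE-labelled at high light.

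Loss of NO07G02030 at normal light was addressed by setting the KO-labelled strain against WT, with the reservation that the transcript itself was not called lower. In the KO-labelled libraries 6 genes were higher and 7 lower, of 9912 tested, each by at least 2-fold. NO07G04430 stood at 10.9 ± 2.03 CPM against 0.145 ± 0.086 in WT (mean ± SD, n = 3; log2 fold change 6.15, SE 0.81, adjusted p = 0.00167, edgeR). NO13G03170 stood at 12.2 ± 3.41 CPM against 0.528 ± 0.092 (log2 fold change 4.51, SE 0.51, adjusted p = 0.000464, edgeR). NO03G05480 was lower, at 1.64 ± 0.28 CPM against 10.9 ± 4.77 (log2 fold change -2.72, SE 0.50, adjusted p = 0.0437, edgeR), and so was NO28G00650, at 1.55 ± 0.63 CPM against 10.2 ± 2.37 (log2 fold change -2.70, SE 0.51, adjusted p = 0.0495, edgeR). Of the 54 organelle genes tested edgeR called 0, with 8 at an unadjusted p under 0.05. DESeq2 and limma on TPM also called 0. The 8 photosystem and electron transport genes of the plastid had positive fold changes in 8 of 8 cases, with a median log2 value of 0.93, and 0 of them passed adjusted over the list alone. Their list was called by camera with a preset correlation (adjusted p = 0.00518) but not with an estimated one (adjusted p = 0.419 with an estimated correlation). The 26 plastid-encoded genes matched by symbol, drawn from the same tested plastid genes, had a median of 1.05. Of them 0 members passed adjusted over the list alone. Their adjusted p = 0.000205 became an adjusted p = 0.419 with an estimated correlation. Of the 5 organelle lists added after seeing the data, camera also called plastid gene expression, plastid photosynthesis and respiratory chain genes (adjusted p = 0.00543, 0.00543 and 0.000205), again with 0 members called and an adjusted p = 0.419 with an estimated correlation for each. The organelle share was 253 ± 123 CPM in NL_KO and 124 ± 33.5 in NL_WT. The 13 calls became 689 without NL_KO replicate 1, 40 with DESeq2, 23 without HL_KO replicate 2 and HL_WT replicate 1, and 5 in a fit of the compared groups only. The calls of NO03G05480 and NO28G00650 were lost without NL_KO replicate 2 or 3, or without any one of the NL_WT replicates. They were also lost with the replicate numbers as a block (adjusted p = 0.122 and 0.0716, edgeR), in the fit of the compared groups only (0.145 each), with limma on log2(TPM + 0.1) (0.0925 each) and with the organellar covariate chosen after seeing the data (0.0567 and 0.121), and that of NO28G00650 without the count filter (0.0505).

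The same comparison at high light gave more genes, and most were higher. In the KO-labelled libraries 322 genes were higher and 38 lower than in WT, 240 and 6 of them by at least 2-fold. NO07G04430 was again higher, at 19.4 ± 9.99 CPM against 1.32 ± 1.53 (n = 3; log2 fold change 3.84, SE 0.63, adjusted p = 0.00728, edgeR), as was NO18G00190, at 14.6 ± 4.48 CPM against 1.75 ± 0.37 (log2 fold change 3.06, SE 0.52, adjusted p = 0.00762, edgeR). Over the alternatives the log2 fold change of NO07G04430 ranged from 2.76 to 5.28. NO08G03060 fell to 5.26 ± 1.77 CPM from 22.5 ± 2.26 (log2 fold change -2.09, SE 0.21, adjusted p = 0.000348, edgeR), and NO14G00440 to 7.30 ± 1.52 from 23.8 ± 4.16 (log2 fold change -1.70, SE 0.25, adjusted p = 0.0037, edgeR). Of the 13 genes called at normal light, 7 were called in the same direction at high light, 4 higher and 3 lower, where independent lists would share 0.195 and 0.0268. The libraries compared differ between the light levels, but all calls use 1 spread per gene estimated over all 18 libraries. The overlap is therefore not independent replication. Of the 54 organelle genes edgeR and DESeq2 called 0 and limma on TPM 1, with 5 at an unadjusted p under 0.05 in edgeR. None of the 7 organelle lists was called. Organelle transcripts made up 174 ± 77.5 CPM in HL_KO and 141 ± 82.3 in HL_WT. The 360 calls became 17 without HL_WT replicate 2, 42 without HL_WT replicate 3, 590 without HL_WT replicate 1, 708 without HL_KO replicate 1 and 861 with DESeq2, which called 71.0% of them higher against 89.4% here. A fit of the compared groups only called 0, with 871 at an unadjusted p under 0.05 in edgeR and 323 called by DESeq2 on those libraries, and the 4 named calls were lost there; those of NO07G04430 and NO18G00190 were also lost without HL_WT replicate 2.

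The OE-labelled strain was set against WT at normal light to ask what added NO07G02030 changes, although the transcript was not called higher. Genes were called in both directions, 1130 higher and 1085 lower, with 488 and 382 of them changed at least 2-fold. With limma on log2(TPM + 1) 60.1% of calls were higher, against 51.0% here. NO10G03460 had 296 to 686 counts in each of the 6 OE-labelled libraries and 0 counts in each of the other 12. At normal light its mean of 32.8 ± 5.29 CPM (n = 3) was at least 173-fold higher than WT, taking 3 counts in each WT library as the floor. That ID lies in a stretch of IDs whose counts are uncertain, because 6 of them matched another ID within 5% in all 18 libraries. NO03G01740 stood at 25.9 ± 3.18 CPM against 2.43 ± 1.08 (log2 fold change 3.41, SE 0.53, adjusted p = 0.00051, edgeR). NO29G01550 was lower, at 0.0712 ± 0.0617 CPM against 29.4 ± 47.9 (log2 fold change -8.52, SE 1.99, adjusted p = 0.00702, edgeR). NO02G00010 was lower too, at 0.471 ± 0.072 CPM against 63.1 ± 103 (log2 fold change -7.04, SE 1.44, adjusted p = 0.00311, edgeR). In both of these genes NL_WT replicate 1 carried most of the WT signal, 84.8 and 181 CPM, and without it NO29G01550 had a log2 fold change of -4.46 and was no longer called (adjusted p = 0.0853, edgeR). With limma on log2(TPM + 1) NO29G01550 was not called either (-2.68, adjusted p = 0.0886). The called organelle genes changed one way, with 0 of 54 higher and 8 lower. The most abundant organelle gene, psbA, had a higher mean that was not called, 41.4 ± 38.8 CPM in NL_OE and 34.4 ± 6.51 in NL_WT. Among the 8 were tufA (elongation factor of plastid translation; log2 fold change -2.32, SE 0.64, adjusted p = 0.0165, edgeR) and secA (plastid protein translocase; -3.06, SE 0.94). Others were the mitochondrial respiratory chain genes atp6 (ATP synthase; -2.71, SE 0.54), nad2 (NADH dehydrogenase; -3.65, SE 0.98), cob (cytochrome b; -1.94, SE 0.54) and cox2 (cytochrome c oxidase; -1.65, SE 0.49). Apart from tufA these examples had at most 2.33 CPM in NL_WT (cob). In NL_OE secA and nad2 stood at 0.161 and 0.126 CPM, against 1.42 and 1.68 in NL_WT, so their fold changes rest on few counts. The list of 26 plastid-encoded genes had 24 negative fold changes, a median of -1.19 and 2 members called, 0 of them adjusted over the list alone. Camera gave an adjusted p = 0.00525, and an adjusted p = 0.513 with an estimated correlation. The 13 respiratory chain genes were negative in 13 of 13 cases with 4 called (adjusted p = 0.00525, and adjusted p = 0.513 with an estimated correlation). Of the 8 photosystem genes 0 were called, 0 also adjusted over the list alone (median -1.01; camera adjusted p = 0.122). In CPM, the organelle share was 83.4 ± 48.5 in NL_OE and 124 ± 33.5 in NL_WT. The 2215 calls became 1474, 1166 and 1211 without NL_OE replicate 1, 2 and 3, and 1082 and 1316 without NL_WT replicate 1 and 2. They became 3953 without HL_KO replicate 2 and HL_WT replicate 1, and 5119 in a fit of the compared groups only, of which 2122 were among the 2215.

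At high light the OE-labelled strain differed from WT in 1683 genes that were higher and 1501 that were lower, 919 and 361 of them by at least 2-fold. With limma on log2(TPM + 1) 62.1% of calls were higher, against 52.9% here. NO10G03460, under the same reservation, was at least 125-fold higher, at 23.5 ± 8.22 CPM (n = 3) against 0 counts. NO20G02140 stood at 257 ± 30.4 CPM against 9.27 ± 3.85 (log2 fold change 4.79, SE 0.35, adjusted p = 6.23e-07, edgeR). NO29G01550 was lower, at 0.0182 ± 0.0315 CPM against 10.002 ± 12.4 (log2 fold change -8.62, SE 2.33, adjusted p = 0.0111, edgeR). NO03G05480 was lower as well, at 0.395 ± 0.059 CPM against 12.1 ± 4.72 (log2 fold change -4.91, SE 0.57, adjusted p = 2.99e-05, edgeR). Between the 2 light levels 1213 genes were called in the same direction, 706 higher and 507 lower, and 67 in opposite directions. Independent lists would share 192 higher and 164 lower. The real lists are not independent, since both use 1 spread per gene estimated over all 18 libraries. Again 0 of 54 organelle genes were higher, and 18 were lower. Plastid tufA stood at 0.501 ± 0.180 CPM against 11.9 ± 8.97 (log2 fold change -4.54, SE 0.72, adjusted p = 0.000345, edgeR) and mitochondrial cox1 at 3.29 ± 1.46 against 11.6 ± 7.97 (log2 fold change -1.80, SE 0.56, adjusted p = 0.0214, edgeR). Others among the 18 were secA (-5.57, SE 1.30), the protease gene ftsH (-2.35, SE 0.77), the RNA polymerase gene rpoA (-4.62, SE 1.32), the ribosomal protein genes rps2 (-3.98, SE 1.22) and rps10 (-3.06, SE 0.88), and the ATP synthase genes atpI of the plastid (-3.17, SE 1.16) and atp6 of the mitochondrion (-4.21, SE 0.62). These others had at most 1.79 CPM in HL_WT (atp6). In HL_OE secA, rpoA and rps2 stood at 0.0176, 0.0176 and 0.0534 CPM, against 1.24, 0.634 and 0.988 in HL_WT. Such values lie near the floor, so the sizes of these fold changes rest on few counts. All 26 plastid-encoded genes had negative fold changes, with a median of -1.90 and 5 called, 4 of them adjusted over the list alone (camera adjusted p = 0.00357, and adjusted p = 0.498 with an estimated correlation). The 13 respiratory chain genes had 7 called and the same pair of values (adjusted p = 0.00357, and adjusted p = 0.498 with an estimated correlation). The 9 plastid gene expression genes had 4 called (adjusted p = 0.0207, and adjusted p = 0.498 with an estimated correlation) and the 13 plastid photosynthesis genes 1 called (adjusted p = 0.0343, and adjusted p = 0.499 with an estimated correlation). The 8 photosystem genes were negative in 8 of 8 cases with 0 called, 0 also adjusted over the list alone (camera adjusted p = 0.094). The organelle share was 64.7 ± 31.7 CPM in HL_OE and 141 ± 82.3 in HL_WT. The mitochondrial part in CPM was 14.7 ± 6.89 against 42.9 ± 21.6 (exact permutation p = 0.1, the smallest possible, and 0.45 adjusted over 18 tests). The plastid part was 50.0 ± 24.9 against 97.7 ± 60.9 (exact permutation p = 0.3, and 0.54 adjusted over 18 tests). Tests of these parts were not planned. The 3184 calls became 2110 and 2046 without HL_OE replicate 1 and 2. The call of cox1 was lost without HL_OE replicate 1 or 2 or HL_WT replicate 1, with the organellar share as a covariate (-0.74, adjusted p = 0.145, edgeR) and without both HL_KO replicate 2 and HL_WT replicate 1 (-1.10, adjusted p = 0.0602, edgeR). The last 2 fits were chosen after seeing the data, and the covariate holds the counts of cox1 itself, which shrinks its fold change by construction. The call of NO29G01550 was lost with limma on log2(TPM + 1).

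**Figure D4:**
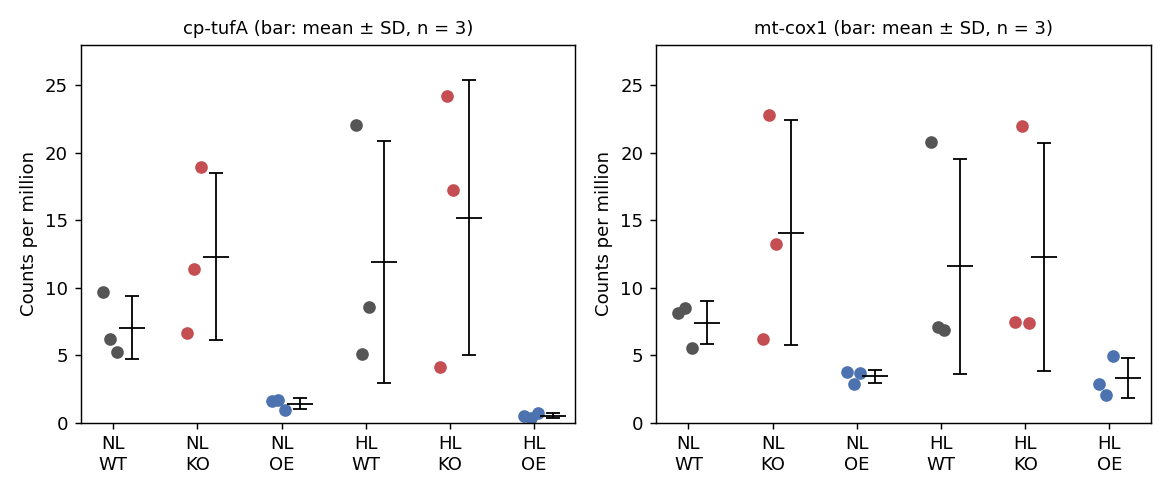
CPM (vertical axis) of the plastid gene tufA and the mitochondrial gene cox1 in each library, by group (horizontal axis); points are libraries and bars the mean ± SD of 3. The OE-labelled groups have the lowest means, 0.501 and 1.40 CPM for tufA and 3.29 and 3.43 CPM for cox1.

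The response of WT to high light comprised 469 higher and 854 lower genes, and the large changes were mostly decreases: 55 rose and 565 fell by at least 2-fold. Of all calls 35.4% were higher, and 44.4% with limma on log2(TPM + 1). NO03G00260 rose to 60.8 ± 14.7 CPM from 13.7 ± 3.40 (n = 3; log2 fold change 2.15, SE 0.30, adjusted p = 0.00129, edgeR) and NO02G05730 to 14.9 ± 3.26 from 3.70 ± 0.64 (log2 fold change 2.00, SE 0.25, adjusted p = 0.000824, edgeR). NO15G02830 fell to 11.2 ± 7.95 CPM from 177 ± 25.9 (log2 fold change -4.00, SE 0.59, adjusted p = 0.00137, edgeR) and NO19G02180 to 1.39 ± 0.39 from 11.7 ± 7.91 (log2 fold change -3.07, SE 0.57, adjusted p = 0.00302, edgeR). NO07G02030 itself was called lower at high light, with a log2 fold change of -0.70 (SE 0.22, adjusted p = 0.0453, edgeR). The call was lost without HL_WT replicate 1 or 2 or any one NL_WT replicate, and without both HL_KO replicate 2 and HL_WT replicate 1. It was also lost in a fit of the compared groups only, with the replicate block and with limma on TPM. The adjusted p (edgeR, DESeq2 or limma) ranged from 0.0172 to 0.18 over all alternatives. Of the 54 organelle genes edgeR called 0, with 3 at an unadjusted p under 0.05, DESeq2 called 1 and limma on TPM 2. None of the 7 organelle lists was called, and the organelle share was 141 ± 82.3 CPM in HL_WT and 124 ± 33.5 in NL_WT. The 1323 calls became 854 without HL_WT replicate 2, and 599 and 648 without NL_WT replicate 1 and 2. A fit of the compared groups only called 211 (206 of them among the 1323), and NO19G02180 was not called there (adjusted p = 0.0578, edgeR).

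The KO-labelled strain at high against normal light had 175 higher and 107 lower genes, 50 and 33 of them by at least 2-fold. NO03G03330 rose to 10.8 ± 1.91 CPM from 2.20 ± 1.48 (n = 3; log2 fold change 2.31, SE 0.57, adjusted p = 0.0415, edgeR) and NO20G02440 to 34.5 ± 6.45 from 8.66 ± 3.40 (log2 fold change 1.99, SE 0.33, adjusted p = 0.0106, edgeR). NO25G01130 fell to 7.71 ± 3.33 CPM from 29.2 ± 4.82 (log2 fold change -1.91, SE 0.26, adjusted p = 0.00198, edgeR) and NO05G04670 to 70.3 ± 17.0 from 245 ± 51.2 (log2 fold change -1.80, SE 0.23, adjusted p = 0.00144, edgeR). One organelle gene was called, psbB, which encodes a core antenna protein of photosystem II (log2 fold change -2.59, SE 0.65, adjusted p = 0.0441, edgeR). The photosystem list had 7 negative members of 8, a median of -1.35, and 1 called, also adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.881 with an estimated correlation). The 26 plastid-encoded genes had a median of -0.82 and 1 called, also adjusted over the list alone (adjusted p = 0.0332, and adjusted p = 0.881 with an estimated correlation). The 13 plastid photosynthesis genes had a median of -1.27 (adjusted p = 0.0116, and adjusted p = 0.881 with an estimated correlation). Organelle transcripts made up 174 ± 77.5 CPM in HL_KO and 253 ± 123 in NL_KO. The 282 calls became 1187, 138 and 500 without HL_KO replicate 1, 2 and 3, and 145 and 13 without NL_KO replicate 2 and 3. NO03G03330 and NO20G02440 were not called without NL_KO replicate 3, and the former was not called without HL_KO replicate 2 or NL_KO replicate 1 or with the replicate block. DESeq2 called 880, a fit with the organellar share as a covariate 857 and a fit with the replicate block 153. A fit of the compared groups only called 0, the named genes included (733 at an unadjusted p under 0.05 in edgeR, 34 by DESeq2).

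In the OE-labelled strain 11 genes were higher and 22 lower at high light, 3 and 13 of them by at least 2-fold. NO20G02440, also called in the KO-labelled strain, rose to 29.0 ± 7.51 CPM from 8.19 ± 1.80 (n = 3; log2 fold change 1.82, SE 0.33, adjusted p = 0.0295, edgeR) and NO04G01220 to 18.4 ± 2.34 from 7.79 ± 1.66 (log2 fold change 1.24, SE 0.25, adjusted p = 0.0482, edgeR). NO26G01820 fell to 2.70 ± 0.15 CPM from 26.8 ± 13.2 (log2 fold change -3.31, SE 0.49, adjusted p = 0.00779, edgeR) and NO03G01840 to 11.5 ± 0.88 from 46.8 ± 7.22 (log2 fold change -2.02, SE 0.28, adjusted p = 0.00463, edgeR). Of the 54 organelle genes edgeR, DESeq2 and limma on TPM called 0, with 0 at an unadjusted p under 0.05 in edgeR, and none of the 7 lists was called. Over all tested genes the median absolute log2 fold change was 0.14 here, 0.27 in the KO-labelled strain and 0.30 in WT, values that also grow with the spread between replicates. A fit of the 6 OE-labelled libraries alone, with their own smaller spread, called 2155 genes, including the 33, and DESeq2 called 141. With the replicate numbers as a block 11 were called, 1 higher and 10 lower. Leaving out HL_OE replicate 1, 2 or 3 left 0, 1 and 7 calls (for 0: 424 at an unadjusted p under 0.05 in edgeR, 59 by DESeq2). Leaving out NL_OE replicate 1, 2 or 3 left 7, 5 and 6. Each named gene lost its call in at least 2 of these fits, and NO04G01220 also with RLE scaling, the replicate block and limma.

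Light responses of the 3 strains shared more called genes than independent lists would. Of the 1323 genes called in WT, 93 were called in the same direction in the KO-labelled strain, where independent lists would share 17.5, and 17 in the OE-labelled strain, where they would share 2.42. Those expectations take every gene as equally likely to be called, although all comparisons use 1 shared spread per gene. Across genes the WT and KO-labelled light changes also both correlated with the axis along which KO-labelled replicates spread (Spearman rho 0.347 and 0.464). The excess alone therefore cannot show a shared light response. In all 3 strains 11 genes were called in the same direction. Leaving out any 1 OE-labelled library left at most 7 calls in that strain, so no more than 7 of the 11 would stay. NO05G04670 was one of these 11, with log2 fold changes of -0.85 in WT, -1.80 in KO-labelled and -1.16 in OE-labelled libraries. NO26G01290 was another, with -0.94, -0.94 and -1.62. Over the 1323 genes the median change in the direction seen in WT was 0.95 in WT, 0.30 in the KO-labelled strain and -0.01 in the OE-labelled strain. These genes were selected on the WT libraries, which inflates their WT value. NO05G04670 and NO26G01290 were singled out after their values were seen.

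The difference between the KO-labelled and WT light responses was tested directly. It was called in 60 genes, 56 with a more positive response in the KO-labelled strain and 4 with a more negative one. NO02G02600 went from 6.81 ± 1.10 to 19.4 ± 11.3 CPM with high light in the KO-labelled strain, and from 12.4 ± 2.36 to 4.53 ± 1.03 in WT (n = 3; log2 difference 2.96, SE 0.46, adjusted p = 0.0216, edgeR). NO15G01410 went from 18.5 ± 2.83 to 37.6 ± 13.8 and from 26.6 ± 8.78 to 9.81 ± 1.43 (2.46, SE 0.42, adjusted p = 0.0284, edgeR). The opposite held for NO07G00340, from 23.8 ± 5.90 to 16.9 ± 0.56 in the KO-labelled strain and from 12.9 ± 0.64 to 23.6 ± 3.52 in WT (-1.36, SE 0.25, adjusted p = 0.0329, edgeR), and for NO29G00670, from 20.6 ± 3.14 to 11.2 ± 2.87 and from 13.2 ± 1.36 to 17.98 ± 0.99 (-1.32, SE 0.26, adjusted p = 0.0403, edgeR). Of the 54 organelle genes edgeR called 0, with 0 at an unadjusted p under 0.05, DESeq2 and limma on TPM called 0, and none of the 7 lists was called. The 60 calls became 0 without HL_WT replicate 1 or 2, NL_KO replicate 3 or NL_WT replicate 1 or 2, 7 without HL_KO replicate 1, 4 without HL_WT replicate 3, 129 without NL_KO replicate 1, 233 without HL_KO replicate 3 and 390 without NL_WT replicate 3. The 4 named genes lost their calls in each fit that called 0, in the fit of the compared groups only and without HL_KO replicate 2 and HL_WT replicate 1, and NO29G00670 also with limma. In those 5 fits 1266 to 1721 genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 175 to 509. With all libraries DESeq2 called 498 (72.5% more positive, against 93.3% here) and limma on log2(TPM + 1) 20.

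The OE-labelled and WT light responses differed in 367 genes, 314 with a more positive and 53 with a more negative response in the OE-labelled strain. NO19G02180 went from 1.74 ± 0.17 to 4.72 ± 1.25 CPM with high light in the OE-labelled strain and from 11.7 ± 7.91 to 1.39 ± 0.39 in WT (n = 3; log2 difference 4.51, SE 0.78, adjusted p = 0.0154, edgeR). NO15G02830 went from 69.5 ± 27.0 to 90.2 ± 13.1 and from 177 ± 25.9 to 11.2 ± 7.95 (4.37, SE 0.77, adjusted p = 0.0154, edgeR). NO06G03960 went from 7.75 ± 0.26 to 3.16 ± 0.54 and from 11.4 ± 3.97 to 29.6 ± 13.7 (-2.66, SE 0.52, adjusted p = 0.0176, edgeR), and NO26G01820 from 26.8 ± 13.2 to 2.70 ± 0.15 and from 4.88 ± 1.76 to 3.09 ± 1.503 (-2.64, SE 0.67, adjusted p = 0.0403, edgeR). Of the 54 organelle genes edgeR, DESeq2 and limma on TPM called 0, with 3 at an unadjusted p under 0.05 in edgeR, and none of the 7 lists was called. The 367 calls became 28 and 34 without HL_OE replicate 1 and 2, 217, 2 and 10 without NL_OE replicate 1, 2 and 3, 8 and 128 without HL_WT replicate 2 and 3, and 56, 21 and 609 without NL_WT replicate 1, 2 and 3. Each named gene lost its call in at least 3 of these fits, and NO26G01820 also with limma on log2(TPM + 0.1) and without HL_KO replicate 2 and HL_WT replicate 1. DESeq2 called 786 (73.5% more positive, against 85.6% here) and a fit of the compared groups only 924.

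The KO-labelled and OE-labelled strains were also compared with each other. At normal light 1721 genes were higher and 1691 lower in the KO-labelled strain, 557 and 802 of them by at least 2-fold. NO13G03170 stood at 12.2 ± 3.41 CPM against 0.823 ± 0.347 in the OE-labelled strain (n = 3; log2 fold change 3.88, SE 0.48, adjusted p = 7.11e-05, edgeR) and NO25G00990 at 22.7 ± 1.77 against 1.66 ± 0.92 (log2 fold change 3.77, SE 0.50, adjusted p = 0.000114, edgeR). NO10G03460 and NO10G03540, both in the uncertain stretch of IDs, had 0 counts in NL_KO and were at least 158-fold and 104-fold higher in NL_OE, with 32.8 ± 5.29 and 21.5 ± 7.96 CPM. The call of NO10G03540 (adjusted p = 0.0474, edgeR) was lost without any one NL_KO or NL_OE replicate, with either other count filter, with the replicate block, with the organellar covariate and with DESeq2, which gave it no adjusted p. At high light the order of the means was the opposite, 201 CPM in HL_KO (0 to 602) against 19.1 in HL_OE. Nearly all of that HL_KO mean came from 1 library, and the other HL_KO libraries lay below every HL_OE library (lowest 12.5). The gene was not called there (adjusted p = 0.151, edgeR). Organelle genes stood higher in the KO-labelled strain, 33 of 54 called and 0 lower. They included tufA (12.3 ± 6.20 against 1.40 ± 0.40 CPM; log2 fold change 3.12, SE 0.64, adjusted p = 0.0025, edgeR), the plastid chaperone gene dnaK (13.4 ± 9.93 against 2.53 ± 0.56; 2.40, SE 0.62, adjusted p = 0.0089, edgeR) and cox1 (14.1 ± 8.35 against 3.43 ± 0.49; 2.03, SE 0.56, adjusted p = 0.0124, edgeR). Among the photosystem genes 5 of 8 rose, also 5 adjusted over the list alone (camera adjusted p = 0.00467, and adjusted p = 0.291 with an estimated correlation), and among the 26 plastid-encoded genes 16 rose, 20 adjusted over the list alone (adjusted p = 1.52e-05, and adjusted p = 0.291 with an estimated correlation). Called members numbered 7 of 9 for plastid gene expression, 6 of 13 for plastid photosynthesis, 2 of 6 for plastid protein quality and transport, 12 of 13 for the respiratory chain and 1 of 5 for mitochondrial ribosomal proteins. The first 4 of these lists were called by camera (adjusted p = 0.00339, 0.00213, 0.0346 and 1.81e-05), and none with an estimated correlation (adjusted p = 0.291 for each with an estimated correlation). In CPM, the organelle share was 253 ± 123 in NL_KO and 83.4 ± 48.5 in NL_OE. The 3412 calls became 1832 and 1940 without NL_KO replicate 2 and 3, 2081 and 2067 without NL_OE replicate 2 and 3, 1083 with the organellar share as a covariate and 5162 without HL_KO replicate 2 and HL_WT replicate 1. That covariate holds the counts of tufA, dnaK and cox1, so the loss of their calls with it says little about them. With limma on log2(TPM + 1) 36.8% of calls were higher against 50.4% here. The gene dnaK lost its call without NL_KO replicate 3, and cox1 without NL_KO replicate 2 or NL_OE replicate 2.

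At high light 1906 genes were higher and 1717 lower in the KO-labelled strain than in the OE-labelled one, 676 and 814 of them by at least 2-fold. NO29G01550 stood at 17.1 ± 17.5 CPM against 0.0182 ± 0.0315 (n = 3; log2 fold change 9.39, SE 2.30, adjusted p = 0.00607, edgeR) and NO02G00010 at 25.6 ± 17.8 against 0.396 ± 0.177 (log2 fold change 5.99, SE 1.43, adjusted p = 0.00509, edgeR). NO10G03460 was at least 115-fold lower in the KO-labelled strain, and NO16G03070 stood at 1.97 ± 1.58 against 33.7 ± 10.99 CPM (log2 fold change -4.06, SE 0.61, adjusted p = 0.000307, edgeR). Of the organelle genes 34 of 54 were higher in the KO-labelled strain and 0 lower, with tufA at 15.2 ± 10.2 against 0.501 ± 0.180 CPM (log2 fold change 4.89, SE 0.72, adjusted p = 0.000272, edgeR) and cox1 at 12.3 ± 8.43 against 3.29 ± 1.46 (log2 fold change 1.89, SE 0.56, adjusted p = 0.0155, edgeR). Called members numbered 12 of 26 plastid-encoded genes, also 12 adjusted over the list alone (camera adjusted p = 0.00164, and adjusted p = 0.474 with an estimated correlation), and 2 of 8 photosystem genes, also 2 adjusted over the list alone (adjusted p = 0.107). The counts were 6 of 9 for plastid gene expression, 4 of 13 for plastid photosynthesis, 4 of 6 for plastid protein quality and transport, 10 of 13 for the respiratory chain and 4 of 5 for mitochondrial ribosomal proteins. Camera called these 5 lists (adjusted p = 0.0124, 0.0313, 0.0189, 0.000554 and 0.0176), and none with an estimated correlation (adjusted p from 0.442 to 0.516 with an estimated correlation). The organelle share was 174 ± 77.5 CPM in HL_KO and 64.7 ± 31.7 in HL_OE. With the organellar share as a covariate 1255 of the tested genes were called, and with limma on log2(TPM + 1) 37.0% of calls were higher against 52.6% here. The call of cox1 was lost with that covariate, which holds its own counts, and also without HL_KO replicate 2, without HL_OE replicate 1 or 2 and without both HL_KO replicate 2 and HL_WT replicate 1.

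Some genes differed from WT in the same direction in both manipulated strains. NO13G01090 was higher at both light levels in both, with 52.7 ± 5.21 CPM in NL_KO and 44.9 ± 2.31 in NL_OE against 4.80 ± 0.27 in NL_WT. At high light it had 64.4 ± 18.3 in HL_KO and 49.2 ± 3.26 in HL_OE against 12.7 ± 6.30 in HL_WT (n = 3). NO14G00440 was lower in all 4 comparisons, by log2 fold changes from -1.54 to -3.07. These were the only 2 genes called in the same direction in all 4 comparisons by edgeR, and NO13G01090 was singled out after its values were seen. In a fit of each light level alone, the fold changes of the KO-labelled and OE-labelled strains correlated across genes with r = 0.099 at normal and r = 0.301 at high light; genes are not independent replicates. Simulated groups without any effect, set against shared simulated WT libraries, gave r = 0.502 ± 0.017 and 0.496 ± 0.023 (SD over 20 simulations). The covariance was 0.0343 at normal light, against 0.0333 ± 0.0017 in the simulations, and 0.137 at high light, against 0.0565 ± 0.0036. The differences were 0.00101 and 0.0805. The simulations gave the strains of a light level 1 shared spread per gene and drew genes independently. The real groups differ in spread, with biological coefficients of variation of 7.02%, 18.5% and 27.5% in NL_OE, NL_WT and NL_KO. The simulated values, signs and shared calls therefore cannot stand for what the real shared controls add. No conclusion is drawn from the differences. At normal light 5 genes were called higher in both and 2 lower in both, where independent lists would share 0.92 and 0.724. At high light the numbers were 97 and 5 against 20.5 and 0.716. Those expectations leave out the shared WT libraries. The simulated groups, which share simulated WT libraries but hold no effect, shared 0 calls on average at either light level. The same sign was seen in 48.3% of genes at normal and 55.7% at high light, against 66.7% in the simulations. The 3 WT libraries of a light level cannot be split into 2 parts of at least 2 libraries each, so part of the excess of shared calls may come from the shared controls. With 1 library left out the correlation at normal light ranged from -0.0028 (NL_KO replicate 1) to 0.25 (NL_WT replicate 3). At high light it ranged from 0.116 (HL_KO replicate 1) to 0.391 (HL_KO replicate 2).

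Genes numbered next to NO07G02030 were examined because a change made at the locus could alter its neighbours. Among the 10 tested IDs on each side, 0 were called in the KO-labelled strain at normal light (2 of 20 at an unadjusted p under 0.05 in edgeR, 0 by DESeq2 or limma on TPM). At high light 2 were called, NO07G01950 (log2 fold change 1.33, SE 0.33) and NO07G01980 (1.46, SE 0.29). In the OE-labelled strain 2 were called at normal light, NO07G02080 (1.13, SE 0.32) and NO07G02120 (-0.52, SE 0.16), and 4 at high light, NO07G01960 (-0.81, SE 0.29), NO07G01970 (-0.77, SE 0.21), NO07G01980 (0.79, SE 0.29) and NO07G02080 (1.90, SE 0.33). Of 9258 windows of the same size over all ID prefixes, 100%, 15.5%, 94.4% and 92.4% held as many called genes for the KO-labelled strain at normal and high light and the OE-labelled strain at normal and high light.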

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

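The fit with each strain's own spread was planned, and its use as a test of the light calls was chosen only after the result was seen; the splits and the test of the replicate axis were planned. The light response differed from wild type in 60 genes in the KO-labelled strain and in 367 genes in the OE-labelled strain, by tests of the difference itself (edgeR). In the KO-labelled strain the log2 differences were 2.96 for NO02G02600, 2.46 for NO15G01410, -1.36 for NO07G00340 and -1.32 for NO29G00670. In the OE-labelled strain they were 4.51 for NO19G02180, 4.37 for NO15G02830, -2.66 for NO06G03960 and -2.64 for NO26G01820. For the KO-labelled strain 9 of 50 splits of the libraries within each strain called at least as many genes as the real 60, and the highest of the others called 2570, so chance was not excluded and the libraries hold a structure other than the light level. For the OE-labelled strain 2 of 50 splits called as many, the real 367 and another with 522, a share under 0.05. These splits mix the light levels within each strain, so they stand for no light effect in either strain. A small share therefore cannot tell whether the light responses of the strains differ. Leaving out 1 library moved the 60 to 0 (HL_WT replicate 1 or 2, NL_KO replicate 3, NL_WT replicate 1 or 2; 1266 to 1721 genes at an unadjusted p under 0.05 in edgeR, 175 to 509 called by DESeq2), 4 (HL_WT replicate 3), 7 (HL_KO replicate 1), 129 (NL_KO replicate 1), 233 (HL_KO replicate 3) or 390 (NL_WT replicate 3). It moved the 367 to 28 and 34 (HL_OE replicate 1 and 2), 8 and 128 (HL_WT replicate 2 and 3), 217, 2 and 10 (NL_OE replicate 1, 2 and 3) or 56, 21 and 609 (NL_WT replicate 1, 2 and 3).

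Fewer genes were called for light in the OE-labelled strain (33) than in wild type (1323). With the spread of its own 6 libraries alone the OE-labelled strain had 2155 calls and wild type 211, so the order of the counts may come from 1 spread estimate shared by groups that differ in spread. The wild type light change also correlated across genes with the axis along which KO-labelled replicates spread (Spearman rho 0.347; genes are not independent replicates), and the OE-labelled light change did not (rho -0.0038), so part of the wild type change may follow that axis. Most other comparisons correlated with it as well, with rho of 0.464 for the KO-labelled light change, 0.512 and 0.544 for KO-labelled against WT at normal and high light, 0.383 and 0.645 for KO-labelled against OE-labelled, -0.141 and -0.355 for OE-labelled against WT, and 0.0554 and -0.325 for the KO-labelled and OE-labelled light response differences. A biological difference between the strains stays open, since culture state and strain cannot be separated with these labels.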

How the results depend on the processing

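Of the results for named genes under all alternatives, 762 kept their direction and call, 153 lost the call and 0 reversed. Of the counts per comparison, 119 stayed within 1.5 times the reported count and 80 moved further; the cause was not tested except where fewer libraries were fitted. RLE scaling and the count filters moved no count that far. DESeq2 called 40 (normal light) and 861 (high light) genes for KO-labelled against WT, 880 and 141 for light in the KO-labelled and OE-labelled strains, and 498 and 786 for their light response differences. The replicate numbers do not pair the libraries (14 of 45 same-number correlations exceeded 0.1); as a block they gave 153 and 11 light calls in the KO-labelled and OE-labelled strains. A fit of the compared groups only called 5 (KO-labelled) and 5119 (OE-labelled) against WT at normal light, 0 for KO-labelled at high light, 211, 0 and 2155 for light in WT, KO-labelled and OE-labelled libraries, and 0 and 924 for the light response differences; for the 3 zeros, in that order, 871, 733 and 1031 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 323, 34 and 123. With limma, light in the OE-labelled strain gave 18 on log2(TPM + 1) and 20 on log2(TPM + 0.1), and the KO-labelled light response difference 20, 20 and, without the filter, 21. The organellar covariate, chosen after seeing the data, gave 857 for light in the KO-labelled strain, and 1083 and 1255 for KO-labelled against OE-labelled at normal and high light. Without HL_KO replicate 2 and HL_WT replicate 1, also chosen after seeing the data, the counts were 23 and 3953 against WT at normal light (KO-labelled, OE-labelled), 191 for light in the OE-labelled strain, 0 and 898 for the light response differences (for the 0: 1816 at an unadjusted p under 0.05 in edgeR, 615 by DESeq2) and 5162 for KO-labelled against OE-labelled at normal light.

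The lower NO07G02030 level of WT at high light was no longer called with the block (-0.69, adjusted p = 0.0751, edgeR), the compared groups only (-0.70, adjusted p = 0.0917, edgeR), limma (-0.69, -0.72 and, without the filter, -0.69; adjusted p = 0.0907, 0.0921 and 0.0956) or without both libraries (-0.51, adjusted p = 0.125, edgeR); leaving out 1 library gave -0.82 to -0.51. Its other ranges with 1 library left out that changed a call were -0.72 to -0.21 for KO-labelled against WT and -0.52 to -0.0075 for KO-labelled against OE-labelled at normal light, and 0.62 to 1.16 for the KO-labelled light response difference; each was called only without NL_KO replicate 1. With 1 library left out, calls against WT ranged from 9 to 689 (KO-labelled) and 1082 to 2143 (OE-labelled) at normal light, and 17 to 708 and 2046 to 2841 at high light. For light they ranged from 599 to 1205 (WT), 13 to 1187 (KO-labelled) and 0 to 7 (OE-labelled; for the 0: 424 at an unadjusted p under 0.05 in edgeR, 59 by DESeq2), for the light response differences from 0 to 390 and 2 to 609, and for KO-labelled against OE-labelled from 1832 to 4421 and 2481 to 4500. The correlation of the strains' changes ranged from -0.0028 (reversed, without NL_KO replicate 1) to 0.25 at normal and 0.116 to 0.391 at high light. Of 77 list tests camera called 26, but 0 with an estimated correlation (0 at an unadjusted p under 0.05; fry called 11). The plastid lists share members, so these tests are not independent. Among 5 and 20 IDs on each side of NO07G02030 the OE-labelled strain had 1 and 6 calls at normal and 2 and 9 at high light, and the KO-labelled strain 1 among 5 at high light. Where a library was left out, the remaining pair was assumed to vary like the other groups. Depth limits genes near the filter; organelle genes rest on as few as 40.5 CPM in all in a library.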

Other observations

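Tests of exchanged labels, normalization, gene length, the share of abundant genes, the ends of ID series and clustering by ID of calls other than OE-labelled at normal light were chosen only after the result was seen; depth, the removal of abundant genes, clustering of OE-labelled calls at normal light and the splits were planned. Tests of the organelle share, against the first component and between groups, were not planned. The 7 genes called in the KO-labelled strain at both light levels kept their direction. NO08G03050 and NO08G03060, adjacent IDs, had log2 fold changes of -2.15 and -2.43 at normal light and -2.61 and -2.09 at high light, while in the OE-labelled strain NO08G03050 had values of 0.99 and 0.94 and NO08G03060 of -0.11 and -0.16. NO09G03810 was higher by 2.21 and 2.38. These genes were chosen after their values were seen. The 11 genes called for light in all 3 strains, of which at most 7 would stay without any 1 OE-labelled library, included 3 that rose, NO04G02560 (0.60 in WT, 0.97 in KO-labelled, 0.78 in OE-labelled libraries), NO10G00230 (0.59, 0.59, 0.66) and NO22G00890 (0.43, 0.50, 0.54).

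NO07G02030 did not follow the label overexpression. The tables argue against scaling and filtering, since the highest log2 fold change of OE-labelled against WT over all alternatives was 0.59. An exchange of labels between groups stays open: the highest mean TPM was 1.45 times the lowest among WT, KO-labelled and OE-labelled groups at high light, so no group stood out. The bound of 2-fold set for the test of exchanged labels assumed that the manipulation changes this transcript. Without such a change an exchange could leave no trace in it. A construct or an edit that leaves the transcript level unchanged, or counted reads that miss the construct, stays open and was not tested.

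KO-labelled and WT libraries spread along the first component while OE-labelled ones did not. In HL_WT the spread rests on replicate 1 (-53.4), since replicates 2 and 3 scored -8.18 and -9.74. The tables argue against the number of counted reads in itself (99.6% of the within-group spread kept after thinning to the lowest total). They also argue against gene length (Spearman rho -0.00999 of loading and length across genes). Thinning cannot undo a difference between libraries that goes with their total counts, so such a difference stays open and was not tested. The library with the lowest total had the lowest score in HL_KO (14614662, -56.8), HL_WT (15571954, -53.4), NL_WT (16069583, -16.0) and NL_OE (17132210, 44.5). In NL_KO and HL_OE it did not. Within groups the component followed the log2 organellar share over 18 libraries (r = -0.786, permutation p = 0.00231; rho = -0.734, permutation p = 0.00932; 0.00231 for r adjusted over 2 relations), and without the 2 farthest libraries r was -0.870; by strain it was -0.980 (KO-labelled), -0.9995 (WT) and 0.163 (OE-labelled), 6 libraries each. A role of a few abundant genes stays open: 100.4% of the spread was kept without the 100 most abundant genes, but so few of 9912 genes could hardly have carried a component of log2 values, and within groups the component followed the share of the 100 most abundant genes of each library (r = -0.933, permutation p = 0.00037, 0.00074 adjusted over 2 relations). A difference in culture state or RNA preparation between flasks may underlie it; the labels give no batch, and neither was tested.

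Neighbouring IDs were called together more often than in shuffled orders in 9 of 11 comparisons (adjusted over 11 tests), and not for light in the KO-labelled strain (8 pairs against a median of 4, permutation p = 0.0614) or in the OE-labelled strain (1 against 0, permutation p = 0.0517). At high light 26 adjacent pairs were called in the same direction in the KO-labelled strain, against a median of 10 in shuffled orders (permutation p = 1e-04, the smallest 10000 shuffles can give), and in the OE-labelled strain at normal light 354 against 246 (permutation p = 1e-04, the smallest possible). Genes at the ends of an ID series were called higher in the KO-labelled strain at high light more often (4.75% against 3.06%; Fisher's exact odds ratio 1.58, p = 0.00312, 0.00833 adjusted over 8 tests), but no single direction held. In the OE-labelled strain they were called higher less often at normal light (odds ratio 0.773, adjusted p = 0.0217) and more often at high light (1.23, adjusted p = 0.0197), and lower more often at normal light (1.38, adjusted p = 0.00217) and less often at high light (0.694, adjusted p = 0.000692). IDs may follow chromosome position, which the files do not state.

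In the stretch around NO10G03460, 8 of 31 IDs (25.8%) had at most 3 counts and at least 100 counts in libraries of 1 group, against 17 of 10302 other nuclear IDs (0.165%). Of 8642 IDs at 10 CPM or more, 15 had another ID within 5% in all 18 libraries, 6 of them with the prefix NO10. How reads were shared among these IDs was not tested.

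Splits of 3 against 3 number 10, too few for a share under 0.05. The real and highest other counts were 13 and 5 (KO-labelled against WT, normal light), 2215 and 0 (OE-labelled against WT, normal light), 360 and 3289 (KO-labelled against WT, high light), 3184 and 0 (OE-labelled against WT, high light), 1323 and 160 (light in WT), 282 and 538 (light in the KO-labelled strain), 33 and 0 (light in the OE-labelled strain), and 3412 and 0, and 3623 and 0, for KO-labelled against OE-labelled at normal and high light. The real split was the only 1 of 10 with as many calls, except for KO-labelled against WT at high light and light in the KO-labelled strain, with 2 of 10 each. The split that called 3289 set HL_KO replicate 1 and HL_WT replicates 2 and 3 against the other 3 libraries, which points to a structure of the samples other than strain.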
